A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

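The samples were 8 preparations of total RNA from Saccharomyces cerevisiae, each hybridised to 1 Affymetrix expression array. Per the labels' protocols, RNA was extracted, labelled with biotin and stained with streptavidin-phycoerythrin by the manufacturer's protocol. The submitters' processing notes name MAS5, the manufacturer's algorithm for summarising the probes of a probe set into 1 signal, with neither a version nor a role. The deposited table held 1 log2 signal per probe set and array for 9275 probe sets, and how the authors normalised the arrays against one another is not given in the sources used here. The base of the logarithm was read from the values: they ran from 0 to 14.55 with 2 decimals, which to base 2 gives signals of up to 23988. Between 11 and 17 values per array lay at exactly 0, which looks like a floor. Array medians lay between 7.53 and 7.69, whereas the 2% trimmed means of the antilog values ran from 437 to 673, a 1.54-fold range, so that a common MAS5 target value was not visible. No detection calls were used here, and arrays give no count behind a value, so that the number of arrays limits the precision.

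The groups came from the sample titles, which give strain, condition and a replicate letter, with 2 arrays in each of 4 groups. The design had foreseen linear signals with a pseudocount. Because the table held log2 values, these were used as deposited with no pseudocount, as the design foresaw for log values, and no further scaling was applied. Probe sets were named through the platform's annotation and a RefSeq gene table (assembly R64), which left all symbols as they were. Of the probe sets, 6504 carried 1 gene, 328 carried several and 2443 had no gene listed there. Probe sets with several genes or none were left out of the tests of genes. For the 315 genes with more than 1 probe set, the one with the highest mean over the 8 arrays stood for the gene. Genes were kept where the mean antilog signal over all arrays reached 10% of the mean trimmed mean, which corresponds to a log2 signal of 5.80. This left 5343 of 5656 genes. Among them, 248 were measured by a probe set whose name carries a suffix, such as those that mark sequences shared by similar genes.

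Comparisons were fitted with limma 3.58.1 in R 4.3.3 on the log2 values, with a mean for each of the 4 groups, all 8 arrays sharing 1 estimate of the spread, and an empirical Bayes step with a mean-variance trend. The residual degrees of freedom were 4 and the prior degrees of freedom 5.54. The 5 comparisons were the glucose response in each strain, the strain difference before and after glucose, and the difference between both glucose responses, tested as an interaction. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, and a gene was called at an adjusted p below 0.05. The labels do not state that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. With 2 arrays per group an exact permutation test cannot reach that threshold, and neither a test for outlying samples nor a count of other splits of the samples applies.

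Gene lists were tested with limma's camera, which asks whether the genes of a list changed more in one direction than the other genes, with a preset correlation between genes of 0.01. It was rerun with the correlation estimated for each list, and limma's fry tested each list on its own. For ribosome biogenesis, a linear model of the list means per array, with a mean per group and 4 residual degrees of freedom, gave confidence intervals, also after subtraction of other genes matched on the mean response. The 24 lists covered ribosome biogenesis, RNA polymerases I and III, cytosolic and mitochondrial ribosomal proteins, translation factors, tRNA synthetases, nucleotide, amino acid and ergosterol synthesis, glycolysis, gluconeogenesis with the glyoxylate cycle and beta-oxidation, hexose transporters, the tricarboxylic acid cycle, the respiratory chain, the environmental stress response, glycogen and trehalose, the proteasome, G1 genes, histones, glucose and TOR signalling, mating-type genes, meiosis and strain markers. Both ribosomal protein lists were drawn by name from genes with a probe set of their own, so family members that share probe sets were left out. The 20 lists with at least 5 members above the filter were tested, with adjustment over those 20 in each comparison. Lists of genes that carry promoter motifs were planned and not run, since no genome sequence was used here.

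The strain groups, comparisons, gene lists, a first set of alternatives and the rule for naming genes were fixed before the data were examined. That rule named STB3 and its chromosomal neighbours CDC37 and SEC7 in every comparison. It then named the 5 largest rises and the 5 largest falls among called genes with the same sign in all 4 pairings of arrays. Where no gene was called, it named the 3 smallest p-values in each direction, as values. It added up to 2 called members of each list with the smallest p-values, and the strain markers and mating-type genes as checks of the labels. List members outside this rule, genes called only under another setting, and phosphate genes were chosen after their values were seen.

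Alternatives covered quantile normalisation, median centring, pseudocounts, the filter on dim probe sets, the treatment of several probe sets, the variance model, the samples in the fit, the replicate letter as a block and leaving out each array in turn. Scaling to a common trimmed mean, a further pseudocount, array weights, a pair of block fits restricted to the 3-day arrays and lists without suffixed probe sets were added after seeing the data. That scaling and that pseudocount were the steps foreseen for linear signals, and each was run alone. The fit was tested on simulated data for the 5343 genes, 200 of them changed. For the wild-type glucose comparison, 49.0% of genes changed by 1 on the log2 scale were called and 98.5% of those changed by 2. For the strain comparison at 3 days, 54.0% were called at a change of 1. For the difference between responses, 0% were called at 1 and 89.5% at 2. Unchanged genes called at changes of 1 and 2 numbered 8 and 12, 6 and 15, and 0 and 12 in these comparisons. Every simulated group had the same spread, whereas the real wild-type replicates differed more than those of stb3-null. These shares and numbers may therefore not hold for the real groups. In 50 simulations with independent genes, none of 1000 tests of unchanged lists was called, and a list shifted by -0.50 was called in all 50. Since genes that vary together were not simulated, this does not measure false calls of lists of such genes.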

Results

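The series asked whether deletion of STB3 alters gene expression within 10 min of adding glucose to starved budding yeast. Stb3 is known as a protein that binds the ribosomal RNA processing element, a promoter motif. BY4742, a haploid strain of mating type alpha, and a stb3-null strain were sampled after 3 days in YPD, a rich medium, and 10 min after 2% glucose was added. Each of the 4 groups held 2 arrays, replicates A and B, and 5343 genes were tested.

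Both wild-type pairs of replicates differed more than both stb3-null pairs. The standard deviation of the log2 difference between replicates A and B was 0.577 in wild type at 3 days and 0.549 in wild type after glucose, against 0.261 and 0.278 in stb3-null. In the same order, 411, 368, 5 and 28 genes lay more than 1 apart on the log2 scale. The first principal component held 78.1% of the variance and separated the arrays before glucose from those after it. The second held 7.86%, with both B replicates of wild type at one end. The number of arrays limits the precision, and the p-values measure only the spread between these samples, which may be technical.

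STB3 (YDR169C) was low on every stb3-null array. Its log2 signal was 8.86 ± 0.53 (SD, n = 2) in wild type at 3 days and 8.02 ± 0.57 after glucose, against 3.10 ± 0.28 and 2.66 ± 0.23 in stb3-null. It was lower in stb3-null at 3 days (adjusted p = 1.16e-04) and after glucose (adjusted p = 2.23e-04). Because the stb3-null signals lay below the filter level of 5.80, no fold is given. Its neighbours CDC37 (YDR168W), a kinase chaperone, and SEC7 (YDR170C), an exchange factor of Golgi transport, did not pass in either strain comparison. CDC37 differed by 0.46 at 3 days (adjusted p = 0.648) and 0.28 after glucose (adjusted p = 0.756), and SEC7 by 0.33 (adjusted p = 0.765) and -0.44 (adjusted p = 0.633).

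Genes of the strain background and mating type were read as checks of the labels. URA3 lay between 3.87 and 4.62 and LYS2 between 2.87 and 3.78 on the 8 arrays, and no LEU2 probe set exceeded 6.18. HIS3 reached 11.17 and MET17 reached 13.07. The alpha-factor gene MF(ALPHA)1 lay between 11.09 and 13.20 and the a-factor receptor gene STE3 between 8.12 and 8.92. The a-cell genes STE2, BAR1 and AGA2 stayed at or below 6.01, 5.63 and 5.72, and MFA2 lay between 6.55 and 7.13. MFA1 lay between 6.99 and 7.81 by a probe set shared between similar sequences and reached 3.72 by its other probe set, and the pheromone exporter gene STE6 lay between 5.14 and 6.79. HIS3 rose after glucose by 2.94 in wild type and 2.31 in stb3-null, and MET17 by 3.18 and 2.67. MF(ALPHA)1 rose by 1.46 and 1.47, and STE6 fell by 1.14 and 1.01, the latter passing in 16 of 20 repeats with other processing or with an array left out. After glucose the STE6 signals lay below 5.80, so the size of its fall is uncertain. The smallest changes with other processing or an array left out, in wild type and stb3-null, were -0.41 and -0.38 for STE6. They were 0.61 and 0.69 for MF(ALPHA)1. The other 3 measured alpha-cell genes and the other 2 measured a-cell genes did not pass in either strain. No alpha-cell or a-cell gene and no strain marker passed in the strain comparisons or in the difference between responses.

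**Figure D1:**
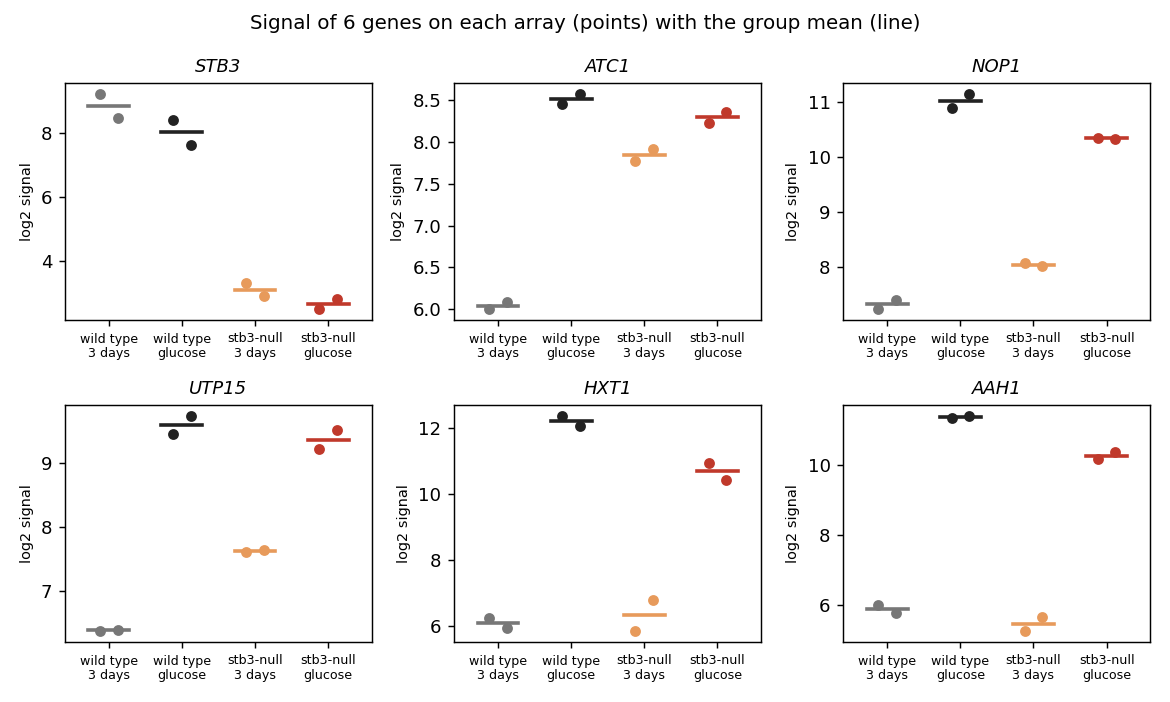
Log2 signal of STB3, ATC1, NOP1, UTP15, HXT1 and AAH1 on each array, with 1 point per array, grouped by strain and condition, and a line at the mean of each group of 2. STB3 lies between 2.5 and 3.30 on the stb3-null arrays and between 7.62 and 9.23 on the wild-type arrays.

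The first comparison asked what 10 min of glucose did in the parent strain. HXT1, which encodes a low-affinity glucose transporter, rose from 6.11 ± 0.21 to 12.23 ± 0.21 (SD, n = 2), a log2 change of 6.12 (SE 0.32, adjusted p = 1.26e-05) or 69.6-fold. With other processing or with an array left out, that change went down to 4.77. AAH1, the adenine deaminase gene that growing cells express, rose from 5.87 ± 0.16 to 11.36 ± 0.06 (SD, n = 2), by 5.50 (SE 0.21, adjusted p = 1.83e-06). SAM1, for S-adenosylmethionine synthetase, rose by 4.64 (SE 0.49), CYS3, for cystathionine gamma-lyase, by 4.63 (SE 0.55) and ANS1 by 4.64 (SE 1.21, adjusted p = 0.0105). The ANS1 signal lay below 5.80 at 3 days (4.32 and 5.61) and at 7.08 and 12.12 in replicates A and B after glucose. Its rise was therefore 2.12 without the latter B array and 7.16 without A, and it did not pass without wild type 3 days replicate A (3.99, adjusted p = 0.0556). The respiratory-growth gene RGI2 fell by 4.16 (SE 0.38, adjusted p = 4.01e-05), and the uncharacterised gene YDL218W fell by 3.90 (SE 0.52). MRK1, a kinase gene of the glycogen synthase kinase family, fell by 3.81, the stationary-phase gene SPG1 by 3.69 and MPF1 by 3.62.

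In all, 2670 genes passed in wild type, of which 1729 were higher and 941 lower after glucose. Among them, 401 rose and 122 fell by more than 2 on the log2 scale. SEC7 rose by 0.92 (SE 0.27, adjusted p = 0.018) and CDC37 by 0.70 (SE 0.25, adjusted p = 0.0396), and STB3 changed by -0.83 without passing (adjusted p = 0.0682). The median of all genes was 0.22, and the split of higher and lower calls depended on how arrays were scaled. It was 1397 to 1256 with quantile normalisation, 1348 to 1276 with median centring and 1004 to 1784 with a common trimmed mean, under which the median of all genes was -0.26. Quantile normalisation took SEC7 to 0.67 (adjusted p = 0.0511) and CDC37 to 0.24 (adjusted p = 0.397). STB3 passed with median centring at -1.05 (adjusted p = 0.0281). Across 21 other settings, which are 13 other ways of processing and 8 omissions of 1 array, SEC7 passed in 16 and CDC37 in 9.

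Most genes for making ribosomes rose in wild type. Of 145 measured ribosome biogenesis genes, 140 rose and none fell, with a median of 2.46. NOP1, which encodes the nucleolar methyltransferase fibrillarin, rose from 7.32 ± 0.12 to 11.02 ± 0.18 (SD, n = 2), and RSA4, for an assembly factor of the large subunit, rose by 3.61 (SE 0.21). Of 80 cytosolic ribosomal protein genes with a probe set of their own, which are not the whole family, 78 rose and none fell (median 1.97), with RPS28B up by 3.48 and RPL37B by 2.39. Among 35 genes of RNA polymerases I and III, 23 rose (median 1.36), with the polymerase I subunit genes RPA12 up by 3.98 and RPA49 by 3.59, and TFC3, of a polymerase III initiation factor, fell by 0.85. Other ways of processing gave medians down to 0.88 for this list, which stayed called. Translation factor genes rose in 31 of 33 cases (median 1.69), as SUP45, the release factor gene, did by 2.46 and GCN3, of the initiation factor exchange complex, by 2.00. Of 20 tRNA synthetase genes 18 rose (median 1.52), with the lysyl enzyme KRS1 up by 3.87 and the methionyl enzyme MES1 by 2.86. Camera with its preset correlation called ribosome biogenesis (adjusted p = 1.28e-32, and adjusted p = 0.45 with an estimated correlation) and cytosolic ribosomal proteins (7.11e-15, and adjusted p = 0.46 with an estimated correlation). It also called the polymerases (adjusted p = 3.15e-05, and adjusted p = 0.46 with an estimated correlation), translation factors (1.98e-08, and adjusted p = 0.45 with an estimated correlation) and tRNA synthetases (2.24e-06, and adjusted p = 0.45 with an estimated correlation). Adjusted over the list alone, 141 ribosome biogenesis genes and 80 cytosolic ribosomal protein genes were higher.

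Many biosynthetic genes rose as well. Of 33 purine and pyrimidine genes, 29 rose (median 1.78), with the CTP synthase gene URA7 up by 4.20 and the GMP synthase gene GUA1 by 3.06, and URA10 fell by 1.08. Of 60 amino acid synthesis genes, 44 rose and none fell (median 1.56), with the sulfate-assimilation gene MET3 up by 3.99 and the serine-synthesis gene SER2 by 3.52. Camera called nucleotide synthesis (adjusted p = 9.77e-08, and adjusted p = 0.45 with an estimated correlation) and amino acid synthesis (3.52e-08, and adjusted p = 0.46 with an estimated correlation). Of 22 ergosterol genes, 12 rose, such as ERG4 by 2.84 and ERG2 by 1.55, and ERG24 fell by 1.03, and the list was not called (median 0.77, adjusted p = 0.115).

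Many genes used for growth on fats and other poor carbon sources fell. In the list of gluconeogenesis, the glyoxylate cycle and beta-oxidation, 17 of 28 genes fell and 1 rose (median -1.26). CTA1, the peroxisomal catalase gene, fell by 3.55 and PXA2, for a subunit of the peroxisomal fatty acid transporter, by 2.25, whereas PCK1, the gluconeogenic carboxykinase gene, rose by 0.78 (adjusted p = 0.0497). Glycogen and trehalose genes fell in 11 of 18 cases and none rose (median -1.20), with PIG2, for a protein that interacts with glycogen synthase, down by -3.11 and the glycogenin gene GLG1 by -2.16. Of 48 stress-response genes, 19 fell and 3 rose (median -0.56), among them the repressor gene XBP1, which fell by 3.25, and UGA1, HSP31 and YGP1, which rose by 2.00, 1.44 and 0.86. Camera called the carbon-source list (adjusted p = 2.77e-06, and adjusted p = 0.474 with an estimated correlation), glycogen and trehalose (8.81e-06, and adjusted p = 0.46 with an estimated correlation) and the stress list (6.23e-05, and adjusted p = 0.578 with an estimated correlation). The stress median was -1.17 without wild type glucose 10 min replicate A and -0.38 without B, and that of glycogen and trehalose -1.74 and -0.65, and both lists stayed called. With quantile normalisation and with a common trimmed mean the stress median was -1.26 and -1.05. The medians of all 10 lists called in wild type kept their signs under quantile normalisation, median centring and the common trimmed mean.

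Central carbon and respiratory genes moved in both directions. HXT3 and HXT4 rose by 3.41 and 2.01 among the 10 measured hexose transporter genes, while HXT5 fell by 1.27 and the glucose sensor gene SNF3 by 2.22 (list median 0.18, mean 0.77, test downward, adjusted p = 0.938). Of 18 glycolytic genes, PFK1, PFK2, FBA1, TPI1 and ADH1 rose by 0.77 to 1.06 and the hexokinase gene HXK1 fell by 1.92 (median 0.49, adjusted p = 0.451). The mitochondrial citrate synthase gene CIT3 fell by 2.65 and IDH2 rose by 0.87, alone among 16 tricarboxylic acid cycle genes (median 0.10, mean -0.08, test downward, adjusted p = 0.432). Of 36 respiratory genes, NDE1, QCR7 and ATP2 rose by 0.96, 0.84 and 0.98 and NDE2 fell by 1.15 (median 0.39, adjusted p = 0.765). With quantile normalisation the respiratory median was -0.40 (adjusted p = 0.00943) and that of the tricarboxylic acid cycle -0.70 (adjusted p = 0.00487). When wild type glucose 10 min replicate A was left out, the medians were 0.04 and -0.40, and the latter list was called downward (adjusted p = 0.0252). When B was left out they were 0.72 and 0.57, and the respiratory list was called upward (adjusted p = 0.0381). The rises of TPI1 and IDH2 did not pass with median centring (adjusted p = 0.0543 and 0.0794). Of 21 other settings, TPI1 and NDE1 passed in 17 each, NDE2 in 16 and IDH2 in 12. NDE2 ranged from -0.51 to -1.79 (adjusted p up to 0.169), NDE1 was at 0.14 with quantile normalisation (adjusted p = 0.619), and HXK1 fell by 1.07 without wild type glucose 10 min replicate B.

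Remaining lists were not called in wild type. Of 39 signalling genes, 9 rose and 11 fell (median -0.32, adjusted p = 0.102, but called with the filter at 40% at adjusted p = 0.016), with the glucose-signalling gene STD1 up by 2.79 and the GTPase gene RAS2 down by -2.23. Of 25 G1 genes, 10 rose and 3 fell (median 0.58, adjusted p = 0.449), with the replication clamp gene POL30 up by 1.76, MCM5 by 1.44 and the cyclin gene CLN2 down by -1.0, along with MBP1 (-0.75) and SVS1 (-0.94). Among 75 mitochondrial ribosomal protein genes, 15 rose and 7 fell, with MRPL11 up by 1.13 and MRPL3 by 1.09 (median 0.12, mean 0.18, test downward, adjusted p = 0.941). The proteasome regulator gene RPN4 fell by 1.36, RPN11 by 0.77 and RPT2 by 0.69, and PRE6 rose by 0.74, among 34 proteasome genes (median 0.15, mean 0.04, test downward, adjusted p = 0.449). The proteasome median was -0.25 without wild type glucose 10 min replicate A (adjusted p = 0.0217), 0.46 without B and -0.27 with quantile normalisation (adjusted p = 0.0226). Of 11 meiosis genes, DMC1, IME1, SPR3, REC8 and SPO73 fell by 0.64 to 1.77 and SSP1 and SPO21 rose by 1.37 and 0.73 (median -0.32, adjusted p = 0.141). Across the other settings DMC1 ranged from -1.86 to -0.57. Of 4 measured histone genes, HTB2 was higher by 0.63 (adjusted p = 0.0343) and HHO1 fell by 0.69. HTB2 passed in only 9 of 21 other settings (0.14 to 0.71, adjusted p up to 0.573), HHO1 in 19 and RPT2 in 15. With a common trimmed mean the medians of the mitochondrial ribosomal proteins (-0.36), hexose transporters (-0.30), tricarboxylic acid cycle (-0.38), respiratory chain (-0.10) and proteasome (-0.34) were negative.

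The same question was asked of the strain without STB3. AAH1 rose from 5.45 ± 0.29 to 10.26 ± 0.13 (SD, n = 2), by 4.81 (SE 0.21, adjusted p = 6.39e-06). Its signals at 3 days (5.24 and 5.65) lay below 5.80, so the size of that rise is uncertain, and it was 3.10 with a pseudocount of 20%. HXT1 rose by 4.36 (SE 0.32, adjusted p = 1.03e-04) or 20.5-fold, and the change went down to 3.18 under other settings. HXT3, another low-affinity glucose transporter gene, rose by 4.01 (SE 0.46), and the small open reading frames YDR034C-A and YKL068W-A by 4.28 (SE 0.40) and 4.11 (SE 0.66). RGI1 and RGI2, both respiratory-growth genes, fell by 3.47 (SE 0.41) and 3.05 (SE 0.38), MRK1 by 3.30 (SE 0.34) and YMR206W by 3.36 (SE 0.20). The signal of the ribosomal RNA gene RDN25-1 fell by 3.70 (SE 0.76, adjusted p = 0.00484). Its change ran from -4.20 to -2.17 under other settings, and whether the amount of this RNA in the cells fell was not tested. RDN25-1 and YDR034C-A were measured by probe sets shared between similar sequences. With the mean of all probe sets of a gene, YDR034C-A rose by 0.69 only (adjusted p = 0.0258). In all, 2112 genes passed, 1492 higher and 620 lower, and 178 rose and 56 fell by more than 2. CDC37 and SEC7 did not pass, at 0.53 and 0.14 (adjusted p = 0.123 and 0.692), nor did STB3, whose signals in this strain lay below 5.80 (adjusted p = 0.332). The median of all genes was 0.26, and the split was 1013 to 815 with quantile normalisation, 1052 to 912 with median centring and 677 to 1475 with a common trimmed mean (median -0.24). The count fell to 1084 without stb3-null 3 days replicate A, 913 without B, 1118 without stb3-null glucose 10 min replicate A and 974 without B. With only the 2 groups compared it was 3285, and with array weights 3255, above the 1845 and 2039 of wild type under the same settings. As reported, all groups shared 1 estimate of the spread, although wild-type replicates differed more than those of stb3-null. The counts therefore do not show in which strain more genes responded.

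Most genes for making ribosomes also rose in stb3-null. Of 145 ribosome biogenesis genes, 135 rose and none fell (median 1.54), with UTP18, of the small-subunit processome, up by 2.68 and SQT1, a chaperone gene for a large-subunit protein, by 2.61. NOP1 rose by 2.29 (SE 0.21) and RSA4 by 2.30. Of 80 cytosolic ribosomal protein genes, 75 rose and none fell (median 1.68), with RPS28B up by 3.40 and RPL6B by 2.64. Among polymerase I and III genes 22 of 35 rose and none fell (median 0.995), with RPC19, of both polymerases, up by 3.27 and RPA12 by 3.14. Translation factor genes rose in 25 of 33 cases (median 1.08), with SUP45 up by 1.82 and the cap-binding protein gene CDC33 by 2.00. Of 20 tRNA synthetase genes 16 rose (median 1.06), with KRS1 up by 2.89 and MES1 by 2.32. Camera called ribosome biogenesis (adjusted p = 2.2e-26, and adjusted p = 0.489 with an estimated correlation), cytosolic ribosomal proteins (1.24e-13, and adjusted p = 0.541 with an estimated correlation) and the polymerases (1.29e-04, and adjusted p = 0.489 with an estimated correlation). It called translation factors (adjusted p = 1.64e-05, and adjusted p = 0.489 with an estimated correlation) and tRNA synthetases (1.95e-04, and adjusted p = 0.489 with an estimated correlation). Adjusted over the list alone, 137 ribosome biogenesis genes were higher and 1 lower. Scaling moved several of these medians. With quantile normalisation they were 0.96 for cytosolic ribosomal proteins and 0.62 for translation factors, and with a common trimmed mean 0.50 for the polymerases, 0.58 for translation factors and 0.56 for tRNA synthetases, and all stayed called.

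Most nucleotide and amino acid synthesis genes rose in stb3-null, and some genes for poor carbon sources and reserve carbohydrates fell. Of 33 purine and pyrimidine genes 23 rose (median 1.34), with URA7 up by 3.16 and the uracil salvage gene FUR1 by 2.06. Of 60 amino acid genes 36 rose (median 1.01), with MET3 up by 2.69 and SER2 by 3.03 from signals below 5.80 (1.68 with a pseudocount of 20%), and SER3 fell by 1.44. In the carbon-source list 13 of 28 genes fell (median -0.66), with CTA1 down by -2.54 and the carnitine acetyltransferase gene YAT1 by -1.39, and PCK1 rose by 1.23. Of 18 glycogen and trehalose genes, GLG1, GLG2, GSY1, GAC1 and PIG2 fell by 1.45 to 2.10 (median -0.73). Of 48 stress genes 13 fell (median -0.07), with SPG1 down by -3.03 and XBP1 by -2.29, and UGA1, UGA2, UBC5 and FMP16 rose by 2.17, 1.58, 1.57 and 0.93. The stress median was -0.19 without stb3-null 3 days replicate B, and -0.18 and -0.15 without stb3-null glucose 10 min replicates A and B. It was -0.87 with quantile normalisation, -0.28 with median centring and -0.56 with a common trimmed mean. Under quantile normalisation and the common trimmed mean, medians were 0.85 and 0.85 for nucleotide synthesis, 0.64 and 0.52 for amino acid synthesis and -1.35 and -1.22 for glycogen and trehalose, and under the latter -1.16 for the carbon-source list. Camera called nucleotide synthesis (adjusted p = 1.12e-05, and adjusted p = 0.489 with an estimated correlation), amino acid synthesis (1.6e-05, and adjusted p = 0.541 with an estimated correlation) and the carbon-source list (2.24e-04, and adjusted p = 0.715 with an estimated correlation). It called glycogen and trehalose (adjusted p = 5.76e-05, and adjusted p = 0.541 with an estimated correlation) and the stress list (0.00151, and adjusted p = 0.716 with an estimated correlation).

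Respiratory genes were higher in 11 of 36 cases and lower in none (median 0.73), with the ATP synthase gene ATP17 up by 1.33 and the cytochrome oxidase gene COX9 by 1.05. Camera called this list (adjusted p = 0.0483, and adjusted p = 0.808 with an estimated correlation), but with quantile normalisation its median was -0.06 (adjusted p = 0.405). Without wild type 3 days replicate A or B, or without any single stb3-null array except 3 days replicate A, it was not called either (adjusted p = 0.0605, 0.062, 0.158, 0.122 and 0.0877), nor with the filter at 40% (adjusted p = 0.126) or the replicate block (0.0544). HXT4 rose by 2.41 and the sensor gene RGT2 by 0.81, and SNF3 fell by 1.48, among hexose transporters (median -0.15, mean 0.90, test upward, adjusted p = 0.951). STD1 rose by 2.71 and RAS2 fell by 2.03 among signalling genes (9 higher, 8 lower, median 0.13, mean 0.09, test downward, adjusted p = 0.35). CIT3 fell by 2.5 and LSC1 and IDH2 rose by 0.86 and 0.81 in the tricarboxylic acid cycle (median 0.41, mean 0.20, test downward, adjusted p = 0.963, but -0.37 and called with quantile normalisation, adjusted p = 0.0293). FBA1 and PFK1 rose by 0.96 and 0.88 and HXK1 fell by 1.71 among glycolytic genes (median 0.30, adjusted p = 0.963, but -0.41 and called with quantile normalisation, adjusted p = 0.00418). Of G1 genes POL30, PCL1 and CLB5 rose by 1.88, 1.51 and 0.94 and CLN2, SVS1 and NRM1 fell by 1.12, 1.22 and 0.65 (median 0.04, mean 0.09, test downward, adjusted p = 0.392).

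Of 75 mitochondrial ribosomal protein genes, 20 rose and none fell, such as MRPL32 by 1.27 and RSM27 by 1.16 (median 0.29, adjusted p = 0.35). Of 22 ergosterol genes 11 rose, such as ERG11 by 1.81 and ERG2 by 1.80 (median 0.63, adjusted p = 0.208). RPN13, PRE6, PRE8 and PUP3 rose by 0.77 to 0.90 among 34 proteasome genes (median 0.36, adjusted p = 0.963), and HTB1 and HTB2 rose by 1.24 and 0.60 among 4 histone genes. The meiotic activator gene IME1 fell by 2.11, DMC1 fell by 1.19 and SSP1 rose by 1.18 among 11 meiosis genes (median -0.34, adjusted p = 0.0727). Camera called that meiosis list in 1 of 11 other ways of processing (adjusted p = 0.0407). Under median centring LSC1, FBA1, HTB1, HTB2, RPN13 and PRE6 did not pass (adjusted p = 0.105, 0.076, 0.0515, 0.191, 0.103 and 0.0893). Of 21 other settings, FBA1, HTB1, PRE6 and LSC1 passed in 14 each, HTB2 in 13, RPN13 in 15, ATP17 and COX9 in 16 each and HXK1 in 17. With a common trimmed mean the medians of the mitochondrial ribosomal proteins (-0.21), glycolysis (-0.20), tricarboxylic acid cycle (-0.08), proteasome (-0.14), G1 genes (-0.46) and signalling genes (-0.37) were negative.

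The responses of both strains were largely shared. Of the genes that passed, 1276 rose in both strains, against 483 for independent calls, and 555 fell in both, against 109. No gene passed in opposite directions, where 201 and 263 would fall together by independent calls. Across the 5343 genes, which are not independent replicates, the responses correlated with r = 0.924 and rho = 0.910, and the slope of stb3-null on wild type along the first axis was 0.775. Of the 2951 genes called in either strain, 98.7% had the same sign. HXT1 rose by 6.12 in wild type and 4.36 in stb3-null, URA7 by 4.20 and 3.16, and RGI2 fell by 4.16 and 3.05.

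**Figure D2:**
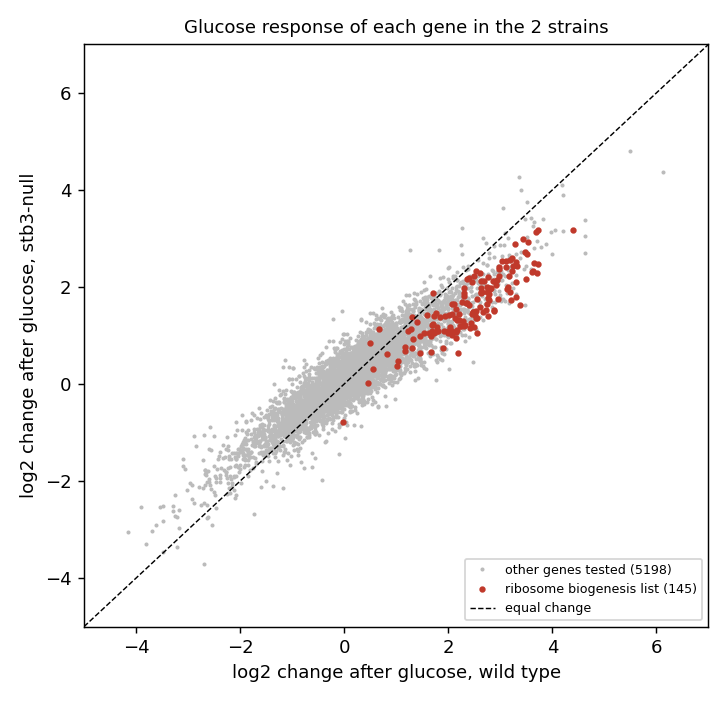
Log2 change after glucose in wild type (horizontal axis) against stb3-null (vertical axis), 1 point per gene, with the 145 ribosome biogenesis genes in red and a dashed line for equal change. Most red points lie to the right of 0 and below the line, and 141 of 145 had a smaller value in stb3-null.

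The strains were then compared before glucose. ATC1 (YDR184C), which encodes a nuclear protein with a role in cation stress, had a log2 signal of 7.84 ± 0.11 in stb3-null and 6.04 ± 0.06 in wild type (SD, n = 2). It was higher by 1.81 (SE 0.18, adjusted p = 0.00585) and, with STB3, was 1 of 2 genes that passed. With a pseudocount of 20% it was higher by 0.95 (adjusted p = 0.0434). Without stb3-null 3 days replicate A or B, ATC1 did not pass (adjusted p = 0.153 and 0.274), and without wild type 3 days replicate A the count rose to 169. Limma gave an unadjusted p under 0.05 for 466 genes, 275 higher and 191 lower, against 267 by chance. That number depended on the arrays in the fit. It rose without wild type 3 days replicate A and fell to about 267 or below without stb3-null 3 days replicate A or B. Leaving out an array also changes the spread that all comparisons share.

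Ribosome-related lists had positive medians in stb3-null against wild type before glucose. Of 145 ribosome biogenesis genes, 129 lay above 0 with a median of 0.42, and none passed over all genes, whereas 11 were higher when adjusted over the list alone. The difference of the list means per array was 0.418, with a 95% confidence interval of -0.0223 to 0.858 that included 0. NOP1 was at 8.04 ± 0.04 in stb3-null and 7.32 ± 0.12 in wild type (SD, n = 2). UTP15 differed by 1.24 (adjusted p = 0.135) and NOP14, also of the small-subunit processome, by 1.28 (adjusted p = 0.0867). Cytosolic ribosomal protein genes lay above 0 in 79 of 80 cases (median 0.47), but the median was -0.03, no longer called, without wild type 3 days replicate A (adjusted p = 0.866) and 0.92 without B. Polymerase genes lay above 0 in 30 of 35 cases (median 0.26), translation factors in 28 of 33 (median 0.33) and tRNA synthetases in 18 of 20 (median 0.41). Other ways of processing gave medians down to 0.25 for ribosome biogenesis and 0.16 for polymerase genes, and both lists stayed called. Mitochondrial ribosomal protein genes lay below 0 in 54 of 75 cases (median -0.12) and the carbon-source list in 20 of 28 (median -0.48). Camera called ribosome biogenesis (adjusted p = 8e-18, and adjusted p = 0.522 with an estimated correlation), cytosolic ribosomal proteins (3.04e-10, and adjusted p = 0.752 with an estimated correlation) and the polymerases (6.65e-04, and adjusted p = 0.522 with an estimated correlation). It called translation factors (4.48e-05), tRNA synthetases (5.64e-05) and, downward, mitochondrial ribosomal proteins (9.34e-04), each at adjusted p = 0.522 with an estimated correlation, and the carbon-source list (1.9e-04, and adjusted p = 0.752 with an estimated correlation).

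Several of those calls rested on 1 array. Without wild type 3 days replicate A, cytosolic ribosomal proteins, the polymerase list (0.26, adjusted p = 0.0866) and mitochondrial ribosomal proteins (-0.08, adjusted p = 0.502) were not called. Without replicate B the carbon-source list was not called (-0.07, adjusted p = 0.494), and without stb3-null 3 days replicate A mitochondrial ribosomal proteins were not (-0.14, adjusted p = 0.0724). The carbon-source list lay at -0.75 without wild type 3 days replicate A, mitochondrial ribosomal proteins at -0.19 without replicate B and cytosolic ribosomal proteins at 0.30 without stb3-null 3 days replicate A. Meiosis genes were called without that stb3-null array (-0.29, adjusted p = 0.0387), and hexose transporters (-0.21, adjusted p = 0.0299) and G1 genes (0.19, adjusted p = 0.0353) without stb3-null 3 days replicate B. No member of the other lists passed at 3 days, and those lists were not called. With other ways of processing, camera called meiosis genes in 1 of 11 (adjusted p = 0.00412) and hexose transporters in 1 of 12 (adjusted p = 0.0253). The medians of those lists as reported were 0.12 for nucleotide synthesis (adjusted p = 0.748), 0.10 for amino acid synthesis (0.749), 0.08 for glycolysis (0.97), -0.14 for hexose transporters (0.159), 0.04 for the tricarboxylic acid cycle (0.97) and 0.03 for the respiratory chain (0.842). They were 0.14 for stress genes (adjusted p = 0.349), 0.18 for glycogen and trehalose (0.503), 0.07 for the proteasome (0.503), 0.16 for G1 genes (0.227) and -0.31 for meiosis (0.0658). Signalling genes had a median of 0.01 and a mean of -0.03 (test downward, adjusted p = 0.511) and ergosterol genes a median of -0.03 and a mean of 0.01 (test downward, adjusted p = 0.749). The 4 histone genes lay below 0, and 1 was lower when adjusted over the list alone.

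The strains were compared again 10 min after glucose, when STB3 alone passed among the genes tested. Limma gave an unadjusted p under 0.05 for 513 genes, 269 higher and 244 lower, but for 926 without wild type glucose 10 min replicate A and 140 without stb3-null glucose 10 min replicate A. Without wild type glucose 10 min replicate A the count was 55, and without stb3-null glucose 10 min replicate B it was 2, STB3 and DAL4. Ribosome biogenesis genes, whose median had been positive before glucose, now lay below 0 in 136 of 145 cases (median -0.34). NOP1 differed by -0.69 (adjusted p = 0.385), UTP15 by -0.23 (adjusted p = 0.741) and NOP14 by -0.26 (adjusted p = 0.684). HXT1 differed by -1.54 (adjusted p = 0.253) and AAH1 by -1.11 (adjusted p = 0.249), and ATC1 by -0.22 (adjusted p = 0.723). Nucleotide synthesis genes lay below 0 in 28 of 33 cases (median -0.42), of which 9 were lower when adjusted over the list alone, and amino acid genes in 53 of 60 (median -0.34). Translation factors lay below 0 in 28 of 33 cases (median -0.28). Camera called ribosome biogenesis (adjusted p = 7.28e-19), nucleotide synthesis (4.78e-09), amino acid synthesis (4.29e-10) and translation factors (1.09e-04), each at adjusted p = 0.506 with an estimated correlation. The ribosome biogenesis median was -0.53 without wild type glucose 10 min replicate A, -0.21 without B and -0.20 without stb3-null glucose 10 min replicate A. Amino acid synthesis was at -0.72 without wild type glucose 10 min replicate A and at -0.08, no longer called, without B (adjusted p = 0.06).

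Stress and reserve carbohydrate genes lay higher in stb3-null after glucose. Stress genes lay above 0 in 46 of 48 cases (median 0.55), glycogen and trehalose genes in 17 of 18 (median 0.62), respiratory genes in 35 of 36 (median 0.39) and proteasome genes in 30 of 34 (median 0.29). Camera called stress genes (adjusted p = 2.41e-08, and adjusted p = 0.521 with an estimated correlation), glycogen and trehalose (5.89e-06, and adjusted p = 0.521 with an estimated correlation), the respiratory chain (1.29e-05, and adjusted p = 0.527 with an estimated correlation) and the proteasome (3.05e-04, and adjusted p = 0.527 with an estimated correlation). Without wild type glucose 10 min replicate B none of these was called, with medians of 0.10, 0.08, 0.04 and 0.01. Tricarboxylic acid cycle genes had a median of 0.38 (adjusted p = 0.0169, and adjusted p = 0.527 with an estimated correlation) and the carbon-source list 0.28 (0.0479, and adjusted p = 0.711 with an estimated correlation), and both were negative without that array (-0.12 and -0.04). Signalling genes were at 0.20 (adjusted p = 0.042, and adjusted p = 0.521 with an estimated correlation). Polymerase genes were at -0.12 (adjusted p = 0.0467), tRNA synthetases at -0.16 (0.0391) and G1 genes at -0.17 (0.0169), each at adjusted p = 0.527 with an estimated correlation, and meiosis genes at -0.11 (0.0479, and adjusted p = 0.506 with an estimated correlation). These signalling, polymerase, synthetase, G1 and meiosis calls also ended without wild type glucose 10 min replicate B (medians 0.17, -0.04, -0.06, -0.01 and -0.01). Without wild type glucose 10 min replicate A, medians were larger in size, at 0.995 for stress genes, 1.2 for glycogen and trehalose, 0.72 for the respiratory chain, 0.56 for the proteasome, 0.72 for the tricarboxylic acid cycle, 0.58 for the carbon-source list, -0.29 for polymerase genes and -0.33 for tRNA synthetases. Without wild type 3 days replicate A or B, the polymerase, signalling and meiosis lists were not called (adjusted p from 0.0508 to 0.0554). Without stb3-null glucose 10 min replicate A the polymerase list (-0.03, adjusted p = 0.285) and G1 genes (adjusted p = 0.0521) were not called, and meiosis genes were at -0.21. Without stb3-null glucose 10 min replicate B, tRNA synthetases, the carbon-source list, the tricarboxylic acid cycle, signalling genes and meiosis genes were not called (adjusted p = 0.0759, 0.12, 0.067, 0.12 and 0.12), and polymerase and G1 genes were at -0.23 and -0.26. Meiosis genes were not called without wild type glucose 10 min replicate A either (adjusted p = 0.0756). Other ways of processing ended calls as well. The carbon-source list was called in 6 of 12 of them, polymerase genes in 8 of 12 and meiosis genes in 4 of 11, with adjusted p up to 0.0913, 0.0795 and 0.0797. Signalling genes were not called with the mean of all probe sets of a gene (adjusted p = 0.0552), nor G1 genes with the filter at 40% (-0.04, adjusted p = 0.374). Cytosolic ribosomal proteins were at 0.09 (adjusted p = 0.702, but 0.23 and called without wild type glucose 10 min replicate B, adjusted p = 0.0128), glycolysis at -0.09 (0.107, but 0.00473 with quantile normalisation), ergosterol genes at -0.12 (0.0905) and mitochondrial ribosomal proteins at 0.01 (mean 0.01, test downward, 0.77). Hexose transporters had a median of 0.29 and a mean of -0.10 (test downward, adjusted p = 0.77). No histone gene passed (median -0.26).

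The last comparison asked whether the glucose response itself differed between the strains. ATC1 rose by 2.48 in wild type (SE 0.18, adjusted p = 1.56e-05) and differed by 0.45 in stb3-null (adjusted p = 0.0718), a difference of -2.03 (SE 0.25) that did not pass (adjusted p = 0.0858). NOP14 had a difference of -1.55 (SE 0.26, adjusted p = 0.469) and UTP15 of -1.47 (SE 0.28, adjusted p = 0.604), as UTP15 rose by 3.21 in wild type and 1.74 in stb3-null. In the other direction, DFP3 had 1.53 (adjusted p = 0.511), SUE1, of cytochrome c turnover, 1.54 (adjusted p = 0.645) and the meiosis gene SLZ1 1.70 (adjusted p = 0.645). SEC7 and CDC37 had -0.77 and -0.18 (adjusted p = 0.728 and 0.918), and STB3, below 5.80 in stb3-null, did not pass (adjusted p = 0.87). Limma called 0 genes, with 369 at an unadjusted p under 0.05, 136 higher and 233 lower, against 267 by chance. The number with such a p was 913 without wild type 3 days replicate A and 743 without wild type glucose 10 min replicate A, but 150 and 229 without stb3-null 3 days replicates A and B and 120 without stb3-null glucose 10 min replicate A, so no excess over chance held throughout. Without wild type 3 days replicate A, 5 genes passed, ATC1, IMD4, PXA1, SLZ1 and SNR54, and without wild type glucose 10 min replicate A, YMR244W alone passed.

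As a list, ribosome biogenesis genes rose less in stb3-null by camera with its preset correlation. The difference lay below 0 for 141 of 145 genes, with a median of -0.76 (adjusted p = 6.56e-41, and adjusted p = 0.404 with an estimated correlation), and 29 were lower when adjusted over the list alone. The mean log2 signal of the list was 7.41 and 7.53 in wild type at 3 days and 9.70 and 10.03 after glucose, against 7.88 and 7.89, and 9.38 and 9.65, in stb3-null. NOP1, for example, rose by 3.71 in wild type and 2.29 in stb3-null, a difference of -1.41 (adjusted p = 0.645). Translation factors had a median of -0.58 (31 of 33 below 0, adjusted p = 8.34e-10, and adjusted p = 0.404 with an estimated correlation), and tRNA synthetases of -0.55 (20 of 20 below 0, 1.15e-06, and adjusted p = 0.446 with an estimated correlation). Amino acid synthesis had -0.48 (adjusted p = 2.1e-07), nucleotide synthesis -0.40 (2.12e-07) and the polymerases -0.40 (3.37e-05), each at adjusted p = 0.446 with an estimated correlation. G1 genes had -0.36 (adjusted p = 0.00177, and adjusted p = 0.452 with an estimated correlation). Cytosolic ribosomal proteins had -0.35 (adjusted p = 4.39e-06, and adjusted p = 0.609 with an estimated correlation), but 0.09 without wild type 3 days replicate A and -0.82 without B, -0.57 and -0.22 without wild type glucose 10 min replicates A and B, and -0.18 and -0.58 without stb3-null 3 days replicates A and B. The amino acid value was -0.17 without wild type glucose 10 min replicate B and -0.77 without A. Polymerase genes were at -0.26 without stb3-null 3 days replicate A and also without stb3-null glucose 10 min replicate A, G1 genes at -0.24 without the former, and nucleotide synthesis at -0.61 without stb3-null 3 days replicate B. With the filter at 40%, G1 genes were not called (-0.17, adjusted p = 0.138).

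Other lists had positive differences, several of them lists that fell in wild type. The carbon-source list had a median of 0.44 (adjusted p = 9.97e-06), glycogen and trehalose 0.46 (0.00243), stress genes 0.33 (4.09e-04), the respiratory chain 0.36 (0.00131) and mitochondrial ribosomal proteins 0.16 (0.0207), each at adjusted p = 0.609 with an estimated correlation. The proteasome had 0.23 (adjusted p = 0.0283, and adjusted p = 0.646 with an estimated correlation) and signalling genes 0.24 (0.0207, and adjusted p = 0.446 with an estimated correlation). Without wild type glucose 10 min replicate B, medians were 0.01 for the respiratory chain, -0.14 for stress genes, -0.10 for glycogen and trehalose and -0.04 for the proteasome. The mitochondrial ribosomal protein (0.09), G1 (-0.13) and signalling (0.15) calls also ended there (adjusted p = 0.369, 0.106 and 0.106). Without wild type glucose 10 min replicate A the values were 0.66 for the respiratory chain, 0.91 for stress genes, 0.89 for glycogen and trehalose and 0.41 for the proteasome. Without wild type 3 days replicate A, the mitochondrial ribosomal protein (adjusted p = 0.707), glycogen and trehalose (0.104) and proteasome (0.232) calls ended, while the carbon-source list was at 0.69 and signalling genes at 0.39. The carbon-source list was at 0.24 and signalling genes were not called (adjusted p = 0.216) without wild type 3 days replicate B. Without stb3-null 3 days replicate B the carbon-source list was at 0.26, the respiratory chain at 0.18 and signalling genes at 0.11. Mitochondrial ribosomal proteins were not called without stb3-null 3 days replicate A or stb3-null glucose 10 min replicate B (adjusted p = 0.221 and 0.0832), the proteasome without stb3-null glucose 10 min replicate A (0.107) and signalling genes without B (0.0586). Not called were glycolysis (-0.21, adjusted p = 0.198, but called without wild type 3 days replicate B at -0.38, adjusted p = 0.0124, and at 0.055 without A), hexose transporters (0.39, 0.346), ergosterol synthesis (-0.06, 0.345) and meiosis (-0.18, mean 0.03, test downward, 0.979). The tricarboxylic acid cycle lay at the threshold (median 0.35, adjusted p = 0.0501). It was called in 9 of 12 other ways of processing, as with quantile normalisation (0.31, adjusted p = 0.0308), and in 3 of 8 with an array left out. Its median was 0.72 without wild type glucose 10 min replicate A (adjusted p = 4.98e-05) and -0.09 without B (adjusted p = 0.52). No histone gene passed (median 0.26).

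**Figure D3:**
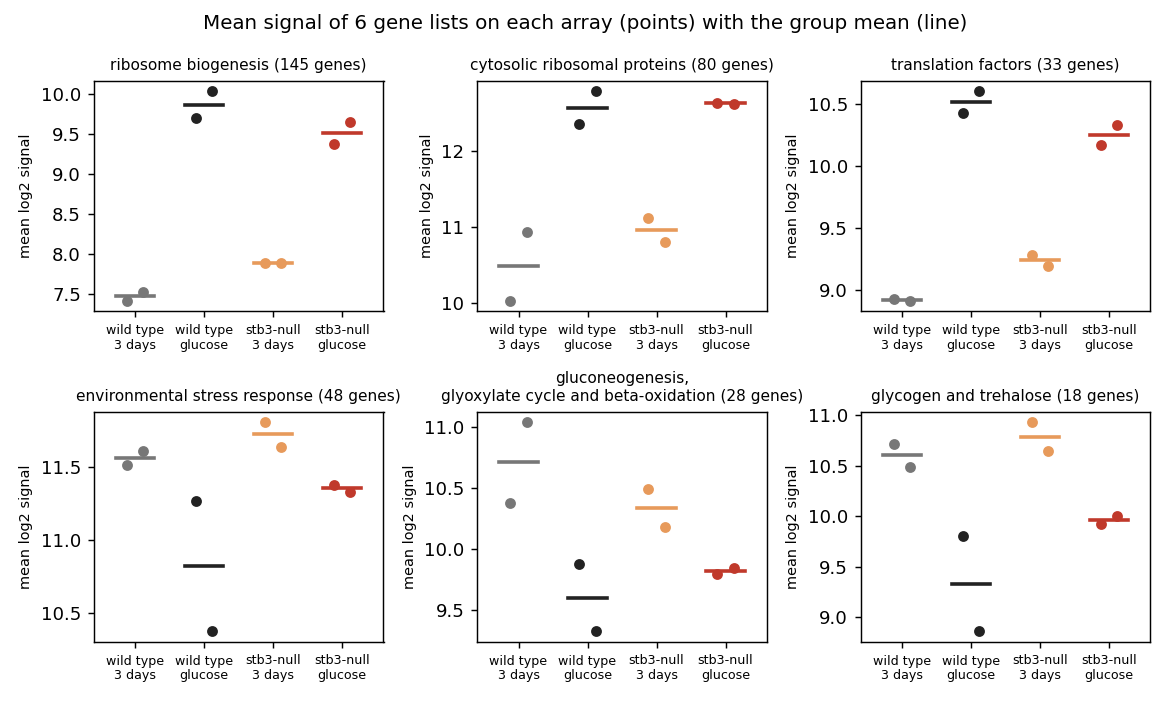
Mean log2 signal of the genes of 6 lists on each of the 8 arrays, grouped by strain and condition, with 1 point per array. The ribosome biogenesis mean lies at 7.88 and 7.89 in stb3-null and 7.41 and 7.53 in wild type at 3 days, and at 9.38 and 9.65 against 9.70 and 10.03 after glucose.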

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

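The tests of a higher level before glucose, of shared variation between arrays and of means per array were chosen only after their results had been seen. Differences between the strains' glucose responses brought 15 lists here, each by camera on the difference itself, and signals in probe sets outside the tests of genes brought 2 more results.

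The median difference between responses of ribosome biogenesis genes was -0.755, against 2.46 in wild type and 1.54 in stb3-null. A single deviating array is argued against, because the value nearest to 0 with any array left out was -0.605. Compression of the whole glucose response stays open: 10000 random sets matched on the mean response had a median of -0.415 (95% range -0.51 to -0.35), which put the list at -0.34 relative to them, but that gap was -0.175 without wild type 3 days replicate A and, with means per array, -0.335 (95% confidence interval -0.714 to 0.0448), within the spread between arrays. A higher level before glucose as the whole difference stays open too, since the list lay at -0.34 after glucose (-0.525 to -0.205 with each array left out), or -0.352 with means per array (95% confidence interval -0.792 to 0.0881), and so does variation between arrays that its genes share, since the difference with means per array was -0.77 (95% confidence interval -1.39 to -0.147, for this list alone) but fry, adjusted over 20 lists, gave adjusted p = 0.186. Loss of STB3 may underlie the smaller response, but with 2 arrays per group it cannot be told apart from these or from differences between cultures or isolates, and genes with the promoter motif that Stb3 binds were not analysed here.

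Other lists with growth-related genes had negative differences: -0.585 for translation factors, -0.55 for tRNA synthetases, -0.48 for amino acid synthesis, -0.40 for RNA polymerases I and III, -0.395 for nucleotide synthesis, -0.365 for G1 genes and -0.35 for cytosolic ribosomal proteins. Positive differences were 0.4625 for glycogen and trehalose, 0.4425 for the list of gluconeogenesis, the glyoxylate cycle and beta-oxidation, 0.365 for the respiratory chain, 0.33 for stress genes, 0.24 for signalling genes, 0.225 for the proteasome and 0.165 for mitochondrial ribosomal proteins. Against matched sets, whose range does not include the spread between arrays, 15 of 20 lists lay outside the 95% range. Beside ribosome biogenesis, those below it were G1 genes (-0.39 relative to the matched median), meiosis (-0.315), translation factors (-0.305), glycolysis (-0.24) and amino acid synthesis (-0.21). Those above it were hexose transporters (0.4125), the respiratory chain (0.375), the tricarboxylic acid cycle (0.31), the carbon-source list (0.2025), the proteasome (0.1725), stress genes (0.1625), signalling genes (0.16), mitochondrial ribosomal proteins (0.145) and cytosolic ribosomal proteins (0.1425).

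Of 977 tested probe sets with no gene listed, 315 passed in the glucose response in wild type, 107 higher and 208 lower, and 228 in stb3-null, 105 higher and 123 lower. Of 289 with several genes listed, 141 passed in wild type, 77 higher and 64 lower, and 132 in stb3-null, 84 higher and 48 lower. These splits were not repeated under other scalings. Between the strains, 1 probe set with no gene listed was higher in stb3-null at 3 days and 1 after glucose. Their calls were not repeated under other settings either.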

How the results depend on the processing

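Scaling to a common trimmed mean, a pseudocount of 5%, array weights, the crossed replicate letters and lists without suffixed probe sets were added as alternatives after seeing the data. That scaling and that pseudocount had been foreseen for linear signals. The promoter motif alternatives were not run. With each array left out in turn, where a lone array is assumed to vary like the other groups, counts ran from 2221 to 2622 for the glucose response in wild type and from 913 to 2523 in stb3-null. They ran from 1 to 169 for the strains at 3 days, from 1 to 55 after glucose and from 0 to 5 for the difference of responses. Of each change given here the cause was not tested, unless stated.

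As reported, all groups shared 1 estimate of the spread, although wild-type replicates differed more, so glucose counts do not rank the strains. The glucose counts in wild type and stb3-null, 2670 and 2112 as reported, were 1845 and 3285 with only the 2 groups compared and 2039 and 3255 with array weights. Their order was also turned without wild type 3 days replicate B (2508 and 2522) and without wild type glucose 10 min replicate B (2221 and 2364). At 3 days 1 gene passed with the filter at 40%, since STB3 was then not tested, and after glucose 0 did (371 at an unadjusted p under 0.05 by limma). With a pseudocount of 20%, 0 passed after glucose (528 at an unadjusted p under 0.05 by limma). With array weights 4 passed after glucose, STB3, PHM6, SPL2 and PHO5, chosen after their values were seen.

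Whether the replicate letters mark a shared day is not given in the sources used here. Differences between A and B correlated across genes at 0.223 between both wild-type groups, 0.129 between both stb3-null groups, -0.182 between strains at 3 days and 0.127 after glucose. With a replicate block the counts were 2660, 2091, 2, 1 and 0. With only the 3-day groups, 16 genes passed with the block as labelled and 91 with the letters crossed in 1 group. These fits left 1 residual degree of freedom, too few to read either count as strain differences.

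Ribosome biogenesis medians of 2.46, 1.54, 0.425, -0.34 and -0.755 (wild-type and stb3-null glucose response, 3 days, after glucose, difference) were not called with an estimated correlation, at adjusted p = 0.45, 0.489, 0.522, 0.506 and 0.404. Fry gave adjusted p = 5.43e-04, 0.00209, 0.28, 0.352 and 0.186.

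A list counts as reversed where the direction of the test changed and either value was called, so the new value itself need not be called. Reversed without wild type 3 days replicate A were cytosolic ribosomal proteins at 3 days (-0.03, up to 0.92 without another array) and in the difference (0.0925, down to -0.82). Without wild type glucose 10 min replicate B, the carbon-source list (-0.04), the tricarboxylic acid cycle (-0.12) and the proteasome (median 0.015, test downward) reversed after glucose, against 0.585, 0.7175 and 0.5575 without replicate A. In the difference, the respiratory chain (median 0.005, test downward), stress genes (-0.14), glycogen and trehalose (-0.0975) and the proteasome (-0.04) did, against 0.6575, 0.9125, 0.885 and 0.405 without replicate A. Quantile normalisation reversed the respiratory chain in wild type (-0.396) and stb3-null (-0.0608) and glycolysis in stb3-null (-0.405). Fry tested hexose transporters in wild type upward (median 0.1825).

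Named genes kept the side of the threshold in 967 of 1040 values with an array left out and 1604 of 1666 under other settings. No called one reversed, but 3 and 4 values that stayed uncalled changed sign. Most named genes were picked for large changes or small p-values, so this does not measure how other called genes fared. With a common trimmed mean, 1945 of 2670 genes called after glucose in wild type stayed called, and 1297 of 2112 in stb3-null. With quantile normalisation 2320 and 1588 did. By camera with the preset correlation, lists kept the side of the threshold, and direction where called, in 737 of 800 and 1153 of 1195 values. Among these, 41 and 36 uncalled values changed sign. With an estimated correlation 58 of 100 lost their call and no list stayed called, so the 42 kept were lists not called before. Fry kept 51 of 100, of which 6 changed sign uncalled, while 42 lost their call, 6 gained a call and 1 reversed. Arrays give no count behind a value, and genes below a log2 signal of 5.80 were not tested.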

Other observations

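The phosphate and chromosome tests were set after strain differences of single genes had been looked at, but before the results they measure were seen. SPL2, PHM6, PHO5 and PHO3 were noticed first and left out of the phosphate list.

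Most of the phosphate-related genes examined lay lower in stb3-null. SPL2, an inhibitor gene of low-affinity phosphate uptake, differed by -1.58 at 3 days and -1.76 after glucose, PHM6 by -1.56 after glucose, and PHO5, an acid phosphatase gene, by -1.07 and -2.10 at these times, and none passed over all genes (adjusted p from 0.135 to 0.509). No exact difference is given for PHM6 at 3 days, since its stb3-null signals (5.56 and 5.73) lay below 5.80. PHO3, another acid phosphatase gene, differed by -0.04 at 3 days (adjusted p = 0.986) and -1.36 after glucose (adjusted p = 0.249). The 11 other members of a phosphate list had a median of -0.34 at 3 days, with 9 of 11 below 0 (camera p = 0.00435, p = 0.125 with an estimated correlation). After glucose it was -0.51, with 11 of 11 below 0 (camera p = 1.62e-06, p = 0.0313 with an estimated correlation). With each array left out the medians ran from -0.46 to -0.235 and from -0.58 to -0.44. The members' estimated correlation was 0.14, so they are not independent of one another or of the genes seen first. By the preset correlation this goes with a shared difference of the phosphate regulon, but variation shared between arrays was not tested for it. Such a difference may reflect STB3 loss, the phosphate left in the medium or an isolate difference, and the design cannot separate these.

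A gained or lost chromosome was tested as a source of the strain differences. The largest chromosome median in size at either time was 0.135, below what a whole extra copy would need, which argues against it. Across genes, strain differences at 3 days and after glucose correlated weakly (r = 0.219, rho = 0.134).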
